A study of Mus musculus with 2 samples.

How the data were processed

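ATAC-seq of whole kidneys from mouse embryos at 14.5 days was analysed from peak lists, in 1 group of 2 biological replicates. Per the labels, both replicates were pools of male and female embryos of the B6N strain, DNA was fragmented by Nextera tagmentation, and reads were placed on the mouse assembly mm10. The authors' own descriptions of each list gave its kind and whether it came from 1 replicate's alignments or from both. The aligner, the peak caller and their versions are not given in the sources used here. Reads and signal tracks were not analysed here.

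Each deposited peak had a signal, the peak caller's enrichment at the summit, which is comparable within a list only. Each deposited peak also had a −log10 p-value of the peak caller, and the deposited score on the narrowPeak scale was used only to check the threshold of the lists. Units and column meanings were taken from the narrowPeak column order and from the range of the values. A region's signal was the highest of its summits, and it was used to describe, rank or filter regions within 1 list and to correlate shared regions between the replicates' lists. Per replicate, the lists used were peaks past the IDR threshold, a lenient list of peaks seen in both pseudoreplicates (random parts of the reads), and the ranked list before any threshold. For the series, the lists used were the conservative set (peaks past the IDR threshold between replicates), the optimal set, the lenient replicated set and the pooled lenient list. The ranked lists of the series were not used. Applying an IDR of 0.05 to each replicate's ranked list gave 36031 and 54796 peaks, of which all but 177 in each were those of its thresholded list.

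Overlapping peaks of a list were merged into regions. Genes came from GENCODE mouse release M21 on GRCm38, with 21853 protein-coding genes that had a protein-coding transcript start on the 21 chromosomes used. A region was a promoter region when it lay within 1 kb of the start of a protein-coding transcript, and otherwise distal, in an exon, an intron or intergenic DNA. Random placements, 100 per list, kept each region's width and chromosome and avoided sequence gaps. A distal region was assigned to the gene with the nearest start, at most 100 kb away, which assigned 8802 of the 11270 distal regions of the conservative set. Coordinates are 1-based.

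Gene lists, families, motifs, rules and tests were chosen before the data were examined, except those said below to have been added or chosen afterwards. There were 22 lists, for 7 parts of the kidney, 11 other cell types or tissues and 4 processes, and 14 families defined by gene symbol. Of all listed genes, only Ahsp of the erythroid list had no match in the annotation. For each list, the mean of log2(1 + distal regions) was compared with 100000 random lists matched gene by gene on the decile of locus length, in a two-sided permutation test. Ratios are mean distal regions per gene over the mean expected from these lists. The share of genes with a promoter region was tested in the same way. The Benjamini-Hochberg method was applied over the 36 lists and families, separately for distal regions and promoters, and a list was called at an adjusted p under 0.05. The smallest two-sided p these permutations can give is 2e-05. Random genes were drawn independently over the genome, so the p-values of families whose genes lie in clusters do not account for the clustering.

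Motifs were searched as 1 consensus each on both strands, for example CCANNAGRKGGC for CTCF, GWAAYHTGAK for SIX1/SIX2, RCATTCCW for TEAD, TTTATKGC for posterior HOX, CCGGAARY for ETS and RRCCAATSR for NFY. A summit window was 151 bp wide and was compared with a flank of the same width centred 1000 bp away that overlapped no peak of the pooled lenient list; 217 of 23656 distal summits had no such flank. The test was a two-sided exact binomial test on pairs with the motif in 1 of the windows only. A motif met the rule when its adjusted p was under 0.05 over 31 motifs and its ratio exceeded that of every version with permuted columns (up to 20 versions, and 8 at the fewest). Ratios and odds had 0.5 added to each count. Promoter and distal summits were compared by two-sided Fisher's exact tests. Summits of 1 region can share sequence, so they are not independent, and p-values over all summits can be too small. Calls that changed with 1 summit per region are given beside the main ones.

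Each value was computed from the conservative set, and from each replicate's own thresholded list for a mean and SD with n = 2. The precision of shares is given as Wilson 95% intervals over regions, and the read depth per sample is unknown. No paired analysis was possible because the series has 1 group. Genes were named by a rule: of each list, the 3 with the most distal regions (ties in alphabetical order) and up to 2 with neither kind of region, the 15 genes with the most distal regions over all genes, the 10 distal regions of highest mean signal rank in the replicates (at most 1 per gene), the 5 strongest regions found in each replicate alone, and Six2, Cited1, Wt1, Pax2, Pax8, Sall1, Ret, Gata3, Foxd1, Hnf1b, Umod and Alb. The Hox genes named singly were chosen after their values were seen.

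Alternatives changed 1 choice at a time, except that X and Y genes and close neighbours were left out together, so that a change there cannot be tied to either. The choices were the peak set, the overlap that counts as shared, the strongest part of a list, 1 replicate left out, the promoter distance, the assignment distance, the matching, gene clusters, the window and flank, and 1 summit per region. Leaving out genes that stand in more than 1 list was added after the data were seen. Sequences of the 10 strongest distal regions and of 200 other distal regions drawn at random were searched with BLAST+ 2.17.0 megablast in the reference and its mitochondrial genome. A match was counted over at least 50% of a region's length at 90% identity or more, or 80% or more for the mitochondrion.

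The methods were tested on simulated data. With 60.4% of regions planted as shared, the overlap found was 60.8%. Of 12 simulated lists of 24 genes each, 0 were called with no planted change, 3 with a planted ratio of 2 and 12 with a planted ratio of 3, so a list of this size with a ratio near 2 is often missed. The simulated lists took genes at random over the genome, so they do not cover families in clusters. Of 22 motifs with nothing planted 1 was called over all summits and 0 with 1 summit per region, and motifs planted in 0.5%, 2% and 5% of windows were called in 2 of 3, 5 of 5 and 1 of 1 cases in both settings. The motif simulation compared the 2 flanks of the same summits with each other. It therefore does not cover calls that arise from a difference in base composition between summits and flanks. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.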

Results

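Open chromatin was measured by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in whole kidneys of mouse embryos at 14.5 days of development. The kidney at this age holds nephron progenitors, early nephrons, the branching ureteric bud and stroma. The series had 1 group with 2 biological replicates, each a pool of embryos of both sexes. Replicate 1 came from 17 embryos, and the number pooled for replicate 2 was not stated. With 1 group and 2 replicates, no test between conditions was possible, so the comparisons are between replicates, genomic places, gene groups and sequence motifs. The values used were peak lists on build mm10 (GRCm38), with overlapping peaks merged into regions. Replicate 1's own list of peaks that passed a reproducibility threshold (IDR, the irreproducible discovery rate) held 35854 peaks in 14664 regions that covered 13.7 Mb. Replicate 2's own list held 54619 peaks in 22091 regions, 1.51 times as many, that covered 20.7 Mb. The conservative set, of peaks reproducible between the replicates, held 61851 peaks in 23832 regions with a median width of 961 bp. Of these regions, 59.7% overlapped replicate 1's own thresholded list and 80.2% replicate 2's. In the lenient lists of replicates 1 and 2 the shares were 97.6% and 99.7%. A conservative region is therefore not always in both replicates' own thresholded lists. Peak lists carry no read counts, so the depth of each library is unknown, and every interval given here covers the counting of regions only.

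The first comparison asked how far the replicates opened the same places. The promoters of all 24 cell cycle genes and all 24 housekeeping genes held a region in each replicate's own list. The promoters of Six2, Cited1, Wt1, Pax2, Pax8, Sall1, Gata3 and Foxd1, genes of kidney progenitors, ureteric bud and stroma, also did so in both. The promoter of Ret, the Gdnf receptor of the ureteric bud, held a region in replicate 2 but not in replicate 1. Of replicate 1's regions, 94.5% (Wilson 95% interval 94.1 to 94.9%) overlapped a region of replicate 2, against 1.70% when regions were placed at random. Of replicate 2's regions, 62.5% (61.8 to 63.1%) overlapped a region of replicate 1, against 1.12% at random. The share fell with signal rank within the list, from 99.7% in the strongest of 5 equal groups to 84.5% in the weakest for replicate 1, and from 97.1% to 30.6% for replicate 2. In the other replicate's lenient list, before the strict threshold, 99.6% of replicate 1's and 93.5% of replicate 2's regions had a match. Across the 13860 regions of replicate 1 shared with replicate 2, the signals of the replicates had a Spearman's rho of 0.861 and a Pearson's r of 0.85 on the log2 scale, and rho was 0.772 over the 3717 distal ones. These are correlations across regions, which are not independent replicates.

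**Figure D1:**
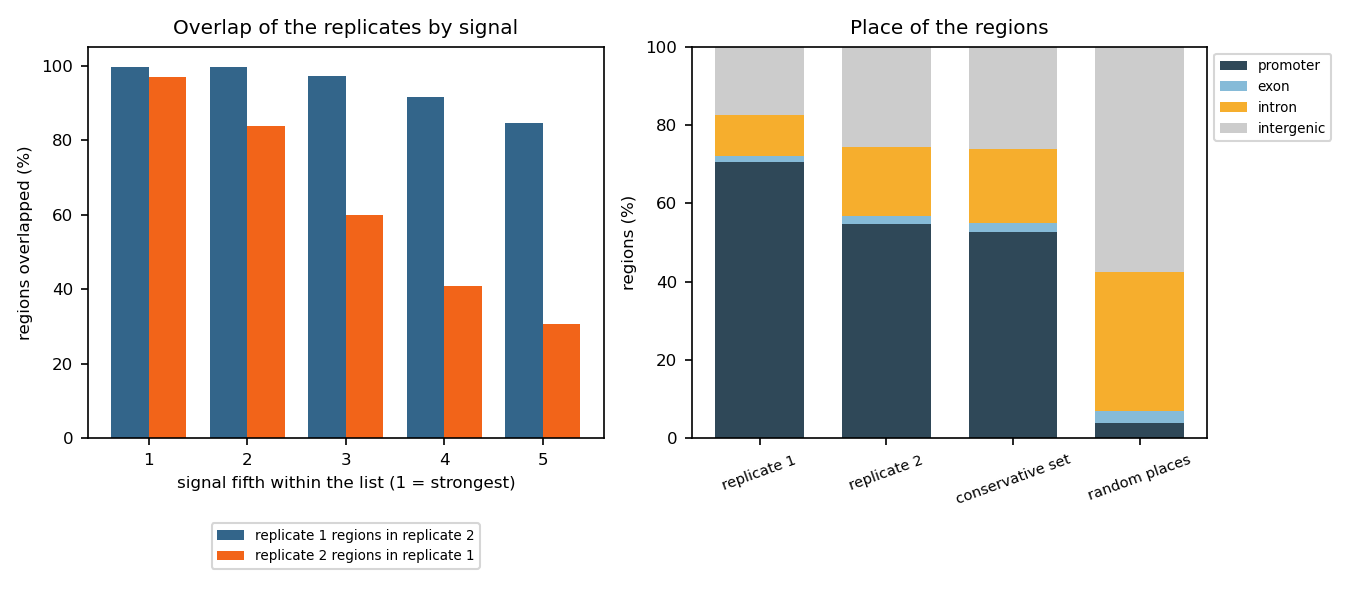
Left, percent of each replicate's regions that overlapped a region of the other, by signal within the list, in 5 equal groups of which 1 is the strongest; right, percent of regions at promoters, in exons, in introns and between genes for each replicate, the conservative set and random places. Overlap fell to 84.5% and 30.6% in the weakest groups, and promoters took 52.7% of the conservative set against 3.80% of random places.

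Regions found in 1 replicate alone were few and mostly away from promoters. Replicate 1 had 54 regions (0.368% of its list) that overlapped no peak of replicate 2's lenient list, and 25.9% of them lay at promoters. Replicate 2 had 1441 such regions (6.52%), of which 9.58% lay at promoters. The strongest of replicate 2 was the promoter of Gpr165, an orphan receptor gene on the X chromosome (X:96713253-96713813, signal percentile 97.3), followed by regions nearest Btg1, Bckdhb, Mum1l1 and Rnase2a. The strongest of replicate 1 was an intergenic region nearest Zfp746 (6:48121168-48121455, percentile 81.9), followed by regions nearest Plcl2, Il1rapl1, Olfr161 and Avpr1b. Each replicate was 1 library, so these differences had no replicate check. Counted against the other replicate's thresholded list instead of its lenient list, the numbers were 804 and 8292.

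The next comparison asked where the reproducible regions lay. Promoters, within 1 kb of a protein-coding start, held 12562 of the 23832 conservative regions (52.7%), 13.9 times the 3.80% of random placements. Introns held 4466 regions (18.7% against 35.6% at random), exons 570 (2.39% against 3.12%) and intergenic DNA 6234 (26.2% against 57.5%). Of the 11270 distal regions, 705 (6.26%) were within 1 kb of the start of a long non-coding RNA, against 1.11% of random placements. Of the 21853 protein-coding genes, 12807 (58.6%) had a promoter region and 5523 (25.3%) had at least 1 distal region assigned to them. Promoter regions had a higher median signal than distal regions in the conservative set (8.45 against 5.72), in replicate 1 (7.92 against 5.97) and in replicate 2 (9.17 against 6.64). The promoter share was 70.6% in replicate 1 and 54.7% in replicate 2, or 62.6% ± 11.3 (SD, n = 2). With as many regions taken from replicate 2 as replicate 1 had, ranked by −log10 p-value, it was 69.9%. The share was 25.5% in the lenient replicated set, which held 66202 regions.

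The 10 distal regions with the highest signal rank in both replicates were narrow and nearly all outside genes. Their median width was 382 bp, against 743 bp over all distal regions, 9 of the 10 were intergenic, and 7 had a single summit. The highest were 35.5 kb from the start of Pak3, a kinase gene (X:143482937-143483180), and 13 kb from that of Abcb11, the bile salt export pump (2:69355469-69355735). These and the regions nearest Frmd4a (2:3964420-3964690) and Hic2 (16:17222195-17222580) matched neither the mitochondrial genome nor another place in the reference. The regions nearest Gm5426 (10:96077546-96077951), G6pd2 (5:60042765-60043140) and Galc (12:97061369-97061856) matched the mitochondrial genome at 97.4%, 97.6% and 99.7% identity. The regions nearest G6pd2, Galc, Myl12b (17:70963584-70963961), Gphn (12:78350798-78351244) and Alkbh8 (9:3258739-3259180) each had at least 1 other place in the reference with 90% identity or more. The gene named with each region is the nearest protein-coding gene, as far as 1766 kb away for G6pd2, and no link between region and gene was measured.

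Gene groups were compared next for the number of distal regions near their members, with 7 lists for parts of the developing kidney. Nephron progenitor genes, of the cells that form nephrons, had 3.10 times as many distal regions as genes with loci of like length (3.82 ± 0.734 in the replicates, SD, n = 2). Podocyte genes, of the filtering cells of the glomerulus, had 2.37 times as many (3.10 ± 0.543, SD, n = 2), and renal stroma genes 2.29 times as many (2.52 ± 0.602, SD, n = 2). These 3 lists held 51 regions at 17 of 24 genes, 35 at 19 of 24 and 43 at 18 of 24. In two-sided permutation tests the p-values were 4e-05 (adjusted 0.00036) for nephron progenitor, 6e-05 (adjusted 0.00036) for podocyte and 0.00014 (adjusted 0.00072) for stroma genes, each with a ratio above 1 in 2 of 2 replicates. The other kidney lists did not pass. Their ratios were 1.57 for renal vesicle and early nephron (permutation p = 0.0303, adjusted p = 0.0991), 1.53 for ureteric bud and collecting duct (adjusted p = 0.3), 1.36 for proximal tubule (adjusted p = 0.318) and 1.28 for loop of Henle and distal tubule (adjusted p = 0.616). Proximal tubule genes had ratios under 1 in both replicates' own lists, 0.484 and 0.924. The stroma call was lost in the stronger part of the set by signal (1.64, adjusted permutation p = 0.528), and the renal vesicle list passed at an assignment distance of 250 kb (2.02). The p-values of gene and motif tests are over genes or summits, not over animals.

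Among nephron progenitor genes, the homeobox gene Uncx had 8 distal regions and no promoter region. It had 6 in replicate 1's own list and 7 in replicate 2's, and the brackets below give such counts, which were made in each list on its own. Bmp7, a growth factor that keeps progenitors alive, had 7 (3 and 5), as did the receptor gene Fgfr1 (4 and 7), while Crym and Hoxc11 had neither kind of region. Foxd1, the transcription factor of stromal progenitors, led the stroma list with 5 (2 and 3), followed by Meis1 with 4 (3 and 3) and Nr2f1 with 4 (2 and 4), while Acta2 and Lum had none. In the podocyte list, which also holds Bmp7, the slit diaphragm gene Kirrel had 3 (0 and 3) and the transcription factor gene Lmx1b 3 (2 and 2). Nphs1 and Nphs2, which encode nephrin and podocin of the mature slit diaphragm, had neither a promoter nor a distal region. Of the lists that did not pass, the Notch ligand gene Jag1 and the receptor gene Notch2 had 4 each and Pou3f3 3, while Irx1 had none. In the replicates' own lists, Jag1 had none in replicate 1's, and Irx1 had 1 in replicate 2's. Wnt11 of the ureteric tips had 5, Wnt7b 4 and the signalling inhibitor Spry1 3, while the water channel gene Aqp2 and Emx2 had none. Osr2 had 3, the endocytic receptor gene Cubn 2 and the water channel gene Aqp1 1, while Cyp2e1 and Cyp4a14 had none. Osr2 and Cubn had no distal region in replicate 1's own list. Mecom had 7, Esrrg 3 and the magnesium channel gene Trpm6 2, while Cldn16 and the potassium channel gene Kcnj1 had none.

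Several kidney regulators had distal regions at some distance from their starts. Six2, which maintains nephron progenitors, had a promoter region and 4 distal ones. Of these, 17:85737002-85738091, 49.3 kb upstream of the start, and 17:85747701-85749273, 60.2 kb upstream, were in both replicates' own lists. Pax2, required for the nephric lineage, had 7 distal regions, the farthest 86.4 kb upstream (19:44669454-44670081). Of the 7, 5 were in replicate 1's own list and 6 in replicate 2's, and 19:44741195-44742600 was in neither. Pax8 had 2, of which the stronger lay 45.9 kb upstream (2:24521326-24522290, signal percentiles 65.7 and 70.0). Foxd1 had 1 that lay 11.9 kb downstream of its start (13:98365653-98366639) with percentiles of 48.6 and 54.3. Wt1, Sall1 and Ret had 1 distal region each, and Cited1 and Gata3 had promoter regions alone. The distal region of Wt1 was in both replicates' own lists, that of Ret in replicate 1's alone and that of Sall1 in neither. Hnf1b had no promoter region and 1 distal region 30.1 kb upstream (11:83819758-83820430), which was in neither replicate's own list. Umod, the gene for uromodulin of the mature thick limb, had no promoter region and 1 exonic region (7:119476509-119477568). Alb, the liver gene for albumin, had none at its promoter and 1 exonic region (5:90467283-90467610) that neither replicate's own list held. Over all genes the most distal regions were assigned to Gse1 with 15, Usp29 with 12, Smad7, an inhibitor of TGF-beta signalling, with 11, and Pkdcc with 10. Counts in this ranking were not adjusted for locus length, and no link between region and gene was measured. Fcgr3, Tenm4, Zfp36l1 and Zfp516 had 9 each. The Notch target Hes1, the Notch coactivator Maml3, Gas1, Hmcn1, Cpn2, 1700001O22Rik and 2010111I01Rik had 8 each.

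Genes of other tissues and of general processes were tested in the same way. Renal Wnt, Fgf, Gdnf and Bmp signalling genes had 2.58 times as many distal regions as matched genes (2.71 ± 0.573 in the replicates, SD, n = 2), with 48 regions at 20 of 24 genes. Gas1 had 8, Bmp7 7 and Wnt11 5, and Fgf2 had neither kind of region. The permutation p was 6e-05 (adjusted 0.00036), higher in 2 of 2 replicates, but 13 of the 24 genes are also in another list, and without these the ratio was 2.04 (adjusted p = 0.159). Housekeeping genes had a ratio of 2.65 (permutation p = 0.00314, adjusted p = 0.0141), with Ywhaz at 4, Eef1a1 at 2 and Pgk1 at 2. Pgk1 had no distal region in either replicate's own list. In the replicates' own lists, housekeeping ratios were 1.86 and 1.53 and did not pass (adjusted permutation p = 0.357 and 0.612). Cell cycle genes (1.76, adjusted permutation p = 0.327, with 0.974 in replicate 2) and genes of human kidney malformation and nephrotic disease (1.37, adjusted p = 0.229) did not pass. Aurkb and Ccnb2 had 3 regions each and Rrm2 2, and among the disease genes Pax2 had 7, Frem1 3 and Itga8 2.

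None of the 11 lists for other cell types and tissues passed for distal regions. Ratios were 1.51 for endothelium (adjusted permutation p = 0.122), 1.40 for macrophage and leukocyte (0.3), 0.509 for erythroid (0.443), 1.17 for neural crest and peripheral neuron (0.514) and 1.59 for adrenal and gonad steroid genes (0.229). They were 1.38 for liver (0.535), 0.860 for skeletal muscle (adjusted permutation p = 1.0), 1.41 for heart (0.258), 1.1 for forebrain (0.58), 0.994 for pancreas and gut (0.82) and 0.943 for pluripotency genes (0.951). Endothelial genes passed in replicate 1's own list (2.31, adjusted permutation p = 0.0195), in the optimal set (1.76, 0.0449), in the lenient replicated set (1.72, 0.00108) and with no matching (1.97, 0.023). Neural crest (1.41, adjusted permutation p = 0.00267) and skeletal muscle genes (1.45, 0.0462) passed in the lenient set. Single members of these lists did have regions: the endothelial genes Ets1 and Fli1 had 3 each and Flt1 2, while Nos3 and Sox18 had none. The macrophage genes Spi1, Fcgr1 and Vav1 had 2 each and C1qb and C1qc none, and the erythroid genes Ank1 and Tal1 had 2 and 1 and Alas2 and Epb42 none. Ednrb had 3, Chga and Gap43 2, Scarb1 3, Cyp11a1 and Fdx1 2, Apob 3, Fgg and Ttr 2, Myl3 3, Gata4 2 and Irx4 1. Bcl11b had 4, Neurod1, Tbr1, Cdx2, Cpa1, Nkx2-2, Nanog and Pax3 2, and Cdh15, Ckm, Esrrb and Lefty1 1. Of the genes with regions in these lists, Flt1, Cdh15 and Lefty1 had no distal region in either replicate's own list. Fli1, Ank1, Fdx1, Gata4, Tbr1, Cdx2, Nkx2-2 and Esrrb had them in replicate 2's alone, and Cyp11a1 and Irx4 in replicate 1's alone. In the conservative set, neither kind of region was found at Ascl1, Dbh, Akr1b7, Cyp11b1, Afp, Ahsg, Acta1, Chrna1, Actc1, Hand1, Gad1, Nkx2-1, Cdx1, Cela1, Ddx4 or Dppa3. Chrna1 and Actc1 had 1 distal region each in replicate 2's own list.

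Among 14 gene families, Hox, Fox and Wnt genes had more distal regions than matched genes, and chemoreceptor genes had fewer. Hox genes, which set position along the body axis, had a ratio of 4.56 (4.29 ± 0.285 in the replicates, SD, n = 2). Fox genes, which encode forkhead transcription factors, had 2.03 (2.14 ± 0.278, SD, n = 2) and Wnt ligands 2.29 (1.81 ± 0.152, SD, n = 2). Olfactory receptors had 0.140 (0.169 ± 0.0236, SD, n = 2) and vomeronasal receptors 0.129 (0.161 ± 0.00443, SD, n = 2). The permutation p was 2e-05, the smallest that the permutations can give (adjusted 0.00024), for Hox genes and both receptor families, 0.00494 (adjusted 0.018) for Fox genes and 0.005 (adjusted 0.018) for Wnt ligands, each in the same direction in 2 of 2 replicates. The rest did not pass: cytosolic ribosomal proteins 0.747 (adjusted permutation p = 0.535), Sox genes 1.28 (0.514), Fgf ligands 1.06 (0.795), collagens 1.28 (0.327), solute carriers 1.08 (0.327), cytochromes P450 0.715 (0.196), claudins 1.11 (0.64), keratin-associated proteins 0.415 (0.229) and Zfp zinc finger genes 1.11 (0.722). Hox genes lie in clusters, and with at most 1 gene per 200 kb and no X or Y genes their ratio was 0.648 (adjusted permutation p = 1.0). This left 1 gene per cluster, Hoxa1, Hoxb13, Hoxc13 and Hoxd13, with 1, 0, 0 and 0 distal regions. These are too few to set against the ratio of the whole family. The permutation p of the whole family counts its 39 genes as independent draws, although neighbours lie in the same clusters. With no matching on locus length the ratio of the whole family was 1.46 and did not pass (adjusted permutation p = 0.235). The Hox ratio was 0.850 in the stronger part of the set by signal, and Wnt ligands did not pass in either replicate's own list (1.92 and 1.70, adjusted permutation p = 0.365 and 0.283), while Zfp genes passed in replicate 1's (1.49, adjusted p = 0.0169) and in the stronger part of the set (1.59, adjusted permutation p = 0.0149). Solute carriers (1.18) and cytochromes P450 (0.561) passed in the optimal set (adjusted permutation p = 0.0278 for each).

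**Figure D2:**
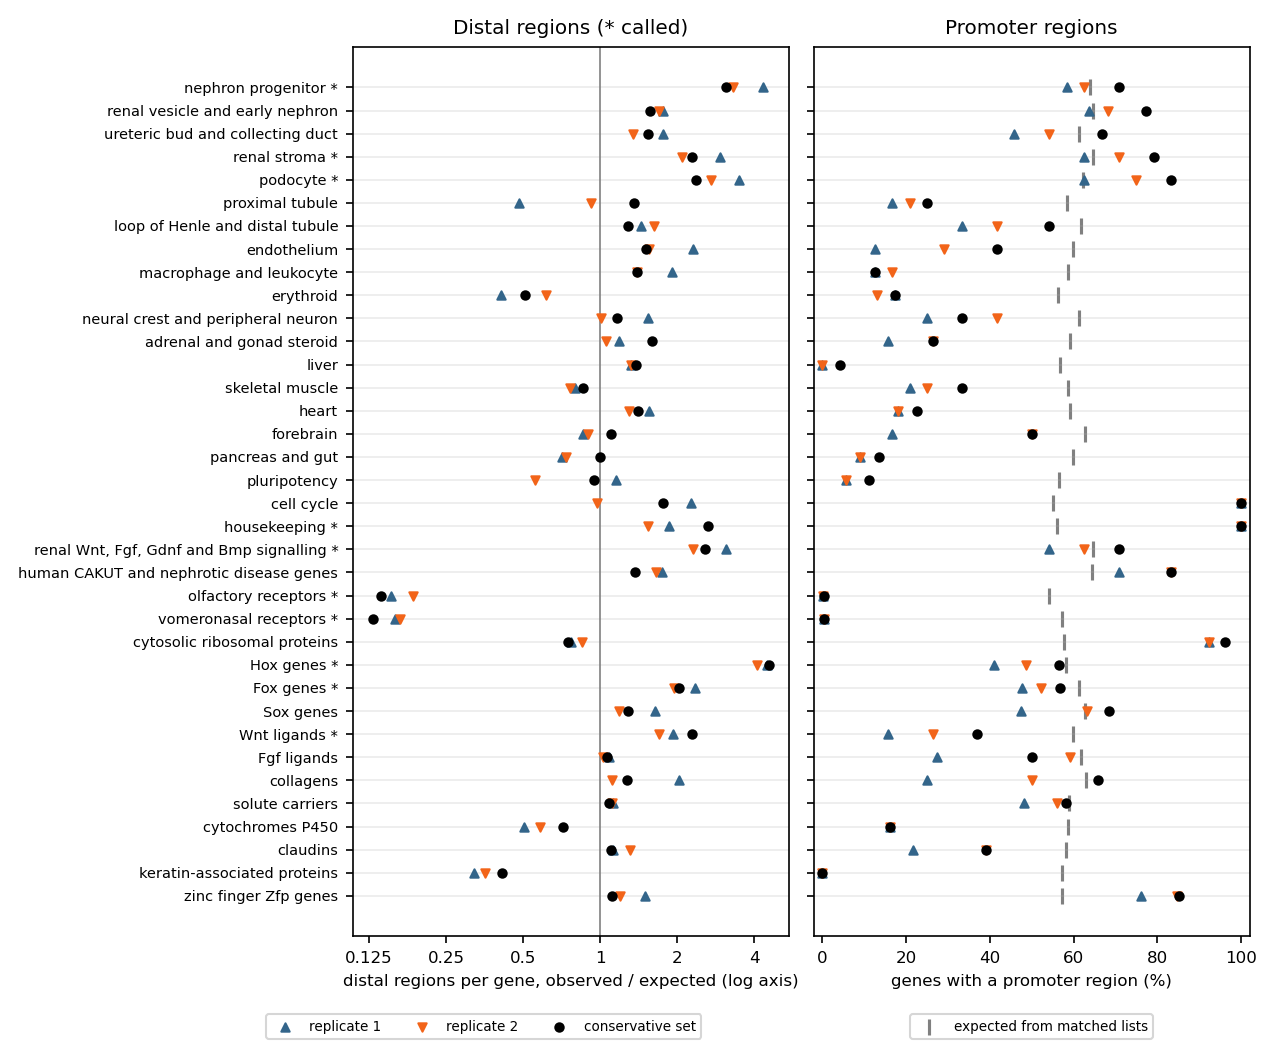
Left, distal regions per gene over the number expected from genes with loci of like length (log axis) for 36 gene lists; right, percent of genes with a promoter region, with the expected percent as a grey bar. Points are replicate 1, replicate 2 and the conservative set. Nephron progenitor, stroma, podocyte and signalling genes stood at 2.29 to 3.10 on the left, and cell cycle and housekeeping genes at 100% on the right.

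Promoters separated the gene groups differently from distal regions. All 24 cell cycle genes and all 24 housekeeping genes had a promoter region, as did 76 of 79 cytosolic ribosomal protein genes (96.2%) and 311 of 365 Zfp genes (85.2%), against 55.0 to 57.7% of matched genes. Genes of mature or other tissues had promoter regions less often than matched genes. This held for 1 of 24 liver genes (4.17% against 56.8%), 3 of 24 macrophage genes (12.5% against 58.6%), 2 of 18 pluripotency genes, 3 of 22 pancreas and gut genes, 4 of 23 erythroid genes, 5 of 22 heart genes, 5 of 19 adrenal and gonad steroid genes, 8 of 24 skeletal muscle genes and 8 of 24 neural crest genes. Proximal tubule genes, most of them transporters and enzymes of the mature tubule, had one at 6 of 24 (58.4% was expected, with 18.8% ± 2.95 in the replicates, SD, n = 2). Promoter regions were also less frequent at olfactory receptor genes (4 of 1133), vomeronasal receptor genes (1 of 326), cytochrome P450 genes (15 of 93) and keratin-associated protein genes (0 of 53). In all, 4 lists were higher, 14 lower and 18 not called in two-sided permutation tests. Against genes matched on promoter GC content as well, 7 of these 18 had fewer promoter regions: endothelium (ratio 0.594, adjusted permutation p = 0.00458), forebrain (0.631, 0.00169), Fox (0.716, 0.000617), Wnt (0.429, 8e-05), Fgf (0.624, 0.0033), solute carrier (0.853, 8e-05) and claudin genes (0.616, 0.0211).

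Adjusted permutation p-values of these promoter calls were 7.2e-05, the smallest that the tests can give here, for cell cycle, ribosomal protein, Zfp, macrophage, liver, pancreas and gut, olfactory, vomeronasal, cytochrome P450 and keratin-associated genes. They were 0.000196 for housekeeping, 0.0006 for pluripotency, 0.000831 for erythroid, 0.00288 for heart, 0.00398 for proximal tubule, 0.0164 for adrenal and gonad steroid, 0.021 for neural crest and 0.0436 for skeletal muscle genes. Each of these 18 lists lay on the same side of its expected share in 2 of 2 replicates. The kidney lists that did not pass had shares of 70.8% for nephron progenitor, 77.3% for renal vesicle, 66.7% for ureteric bud, 79.2% for stroma, 83.3% for podocyte (adjusted permutation p = 0.0862) and 54.2% for loop of Henle genes. Neither did endothelium (41.7%), forebrain (12 of 24), signalling (70.8%), disease genes (83.3%), Hox (56.4%), Fox (56.8%), Sox (68.4%), Wnt (36.8%), Fgf (11 of 22), collagen (65.9%), solute carrier (58.1%) or claudin genes (39.1%). In replicate 1's own list the endothelial, forebrain, Wnt, Fgf, collagen and claudin shares were low enough to pass (ratios of 0.246, 0.313, 0.310, 0.520, 0.473 and 0.436), as were the endothelial and Wnt shares in replicate 2's (0.50 and 0.452), where the neural crest call was lost (0.696). In the lenient replicated set the calls for proximal tubule (0.805), erythroid (0.735), skeletal muscle (0.865), heart (0.670), pancreas and gut (0.661), neural crest (1.07) and adrenal genes (1.01) were lost, and those for neural crest (0.792) and adrenal genes (0.778) also in the optimal set.

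Hox genes are given by cluster, since those of paralogue group 11 are required for kidney development. In the conservative set 22 of the 39 Hox genes had a promoter region (16 in replicate 1 and 19 in replicate 2). These were 9 of 11 genes in the Hoxa cluster, 4 of 10 in Hoxb, 4 of 9 in Hoxc and 5 of 9 in Hoxd. By paralogue number they were 12 of 23 for groups 1 to 8, 8 of 10 for groups 9 to 11 and 2 of 6 for groups 12 and 13. Of group 11, Hoxd11 had a promoter region that was also in both replicates' own lists, Hoxa11 had one that was in replicate 1's alone, and Hoxc11 had none. Of groups 12 and 13, Hoxa13 and Hoxc13 had one, and that of Hoxa13 was in neither replicate's own list. No test was made between clusters or paralogue groups.

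The last comparison asked which transcription factor motifs marked the summits. CTCF, the factor of insulators and loop anchors, had its motif in 888 of 23439 distal summit windows against 155 of the flanks beside them, a ratio of 5.71 (4.62 ± 0.954 in the replicates, SD, n = 2). The E-box CAGCTG, read by basic helix-loop-helix factors, was in 3818 windows (16.3%) against 1656 flanks (7.07%), a ratio of 2.31 (2.55 ± 0.0473, SD, n = 2). The motif of SIX1/SIX2 was in 358 against 151 (2.37, with 2.24 ± 0.304 in the replicates, SD, n = 2). TEAD motifs were in 896 against 626 (1.43), AP-1 motifs in 817 against 621 (1.32) and those of posterior HOX factors in 295 against 227 (1.30). PBX-HOX motifs were in 44 against 14 (3.07, with 7.57 in replicate 1's own list and 5.47 in replicate 2's). SP/KLF (6.30), ETS (2.71) and NFY (1.79) motifs were also more frequent at summits. In the own lists of replicates 1 and 2, these ratios were 8.7 and 7.0 for SP/KLF, 4.3 and 3.0 for ETS, and 2.6 and 1.8 for NFY motifs. Of the 31 motifs, 17 met the rule of an adjusted p under 0.05 and a ratio above every permuted version. Of these, 16 were more frequent at summits, with NFI, WT1/EGR, MAF, MEIS, PAX (23 against 0) and REST (15 against 2) besides those above. Under 8 alternatives, the call was kept in 4 for PAX and MEIS, 5 for WT1/EGR and MAF, and 6 for NFI motifs. It was kept in 7 for CTCF, posterior HOX and PBX-HOX motifs, and in all 8 for the rest of the 16. The POU motif met the rule with fewer summit windows than flanks (221 against 296), since the ratios of its permuted versions were at most 0.660, and against flanks of the same composition its ratio was 1.42. The POU call was kept in 1 of 8 alternatives. The HNF1 motif, which was in 21 summit windows, did not meet the rule in the main test but did in 5 of 8 alternatives, and its ratio against flanks of the same composition was 5.26.

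Adjusted exact binomial p-values were 3.06e-127 for CTCF, 9.99e-216 for the E-box, 5.14e-20 for SIX1/SIX2, 5.31e-12 for TEAD and 2.77e-07 for AP-1 motifs, with a ratio above 1 in 2 of 2 replicates. Over 8 alternatives, 1 summit per region among them, the highest adjusted exact binomial p-values were 3.64e-26, 6.26e-88, 1.82e-05, 1.76e-07 and 0.00502 in the same order. The motifs of NRF1, RFX, AP-2, HNF1, HNF4, TCF/LEF, FOX, NR2F/RXR, MEF2, RUNX, GRHL, GATA, SOX and STAT factors did not meet the rule. Of these, GATA (0.565), GRHL (0.602), STAT (0.694), MEF2 (0.764), SOX (0.794), HNF4 (0.869) and RUNX motifs (0.904) were in fewer summit windows than flanks. Against flanks of the same GC content and CpG number, a comparison added after the data were seen, the ratios were 6.68 for CTCF, 3.95 for SIX1/SIX2, 1.60 for the E-box, 1.58 for TEAD, 1.82 for HOX, 0.946 for GATA and 0.888 for STAT motifs. They were 1.45 for SP/KLF, 1.41 for ETS and 2.05 for NFY motifs. The direction turned for SOX (1.34), HNF4 (0.869 to 1.16), MEF2 (0.764 to 1.92), RUNX (0.904 to 1.03), GRHL (0.602 to 1.07) and POU motifs. WT1/EGR (3.70 to 1.82), AP-2 (2.73 to 1.1), NRF1 (5.44 to 1.90) and REST motifs (6.20 to 3.68) had lower ratios than against flanks beside the summits, while TCF/LEF (1.06 to 1.76), FOX (1.14 to 1.76) and PBX-HOX motifs (3.07 to 9.47) had higher ones. No test was made of the matched ratios, and the matching counted the bases of the motif itself. In replicate 1's own list the CTCF (3.94), WT1/EGR (3.41), HOX (1.22), MAF (1.58), MEIS (1.49) and POU (0.838) motifs did not meet the rule while NRF1 (37.0), RFX (13.7) and SOX (0.739) did; in replicate 2's, MEIS (1.75) and POU (0.760) did not while HNF1 (3.0), FOX (1.17) and SOX (0.828) did. With 1 summit per region, WT1/EGR (4.38), PAX (6.60), POU (0.786) and NFI (5.78) motifs did not meet it, while HNF1 (2.85), FOX (1.24) and SOX (0.785) motifs did.

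**Figure D3:**
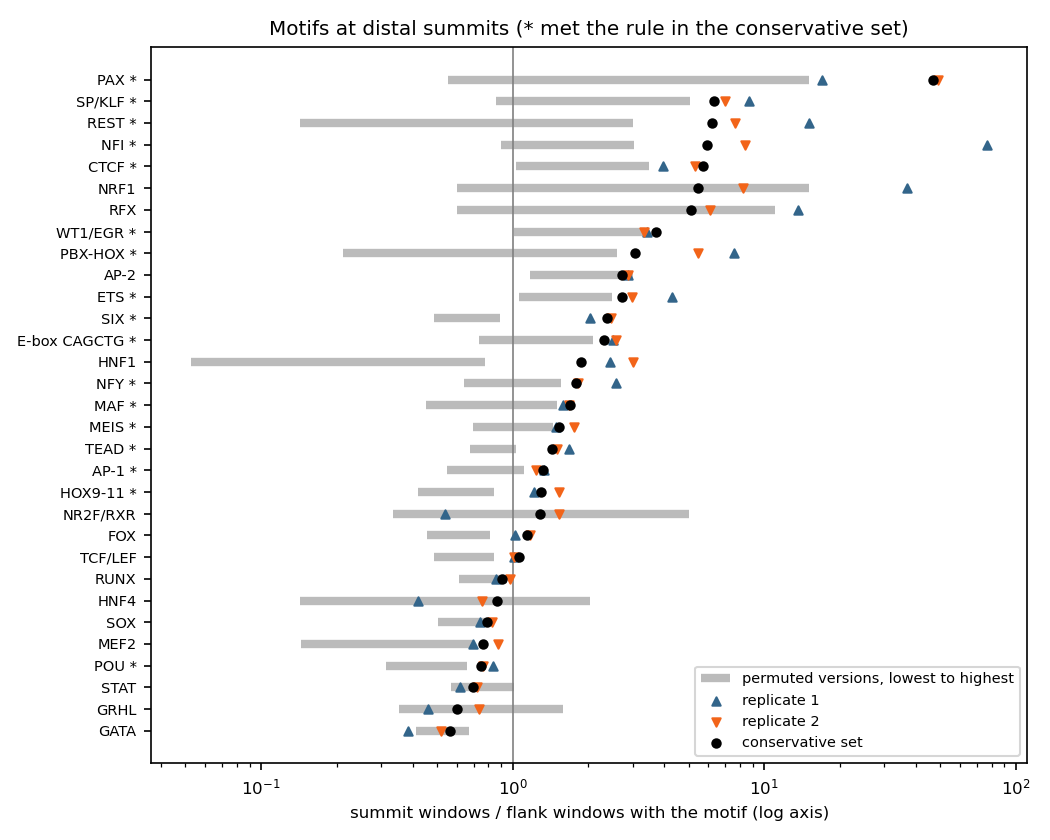
Distal summit windows with each of 31 motifs over flank windows with it (log axis, with 0.5 added to each count), for replicate 1, replicate 2 and the conservative set; grey bars span the permuted versions of the motif. SIX1/SIX2 (2.37 in the conservative set) and CTCF (5.71) lay above every permuted version there, and PAX is plotted from 23 against 0.

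Promoter and distal summits carried different motifs. These counts were matched neither on GC content nor on CpG number, and no permuted versions were compared. The differences below therefore cannot be told apart from differences in base composition. SP/KLF motifs were in 9.56% of 36891 promoter summits against 2.74% of 23656 distal ones, a log2 odds ratio of 1.91 (1.67 ± 0.43 in the replicates, SD, n = 2). ETS (2.09), NRF1 (2.56), NFY (1.11) and AP-2 (0.92) motifs were also more frequent at promoters on the log2 odds scale. Distal summits more often held the motifs of CTCF (−2.21), SIX1/SIX2 (−1.96), posterior HOX (−2.31), PBX-HOX (−2.90), TEAD (−1.38), AP-1 (−1.20) and the E-box (−0.98). In two-sided Fisher's exact tests 5 motifs were more frequent at promoters, 22 at distal summits, and WT1/EGR, RFX, GRHL and REST passed in neither direction. Adjusted Fisher's exact p-values were 8.62e-257 for SP/KLF, 5.4e-136 for CTCF, 4.47e-48 for SIX1/SIX2 and 6.22e-50 for HOX motifs, each in the same direction in 2 of 2 replicates. Over 4 alternatives, 1 summit per region among them, the highest adjusted Fisher's exact p-values were 1.96e-76, 3.76e-42, 3.49e-24 and 9.25e-23 in the same order. The NR2F/RXR difference (−1.31) passed in neither replicate's own list and was 0.11 in replicate 1's. With 1 summit per region the POU (−0.51) and STAT (−0.22) differences turned to 0.14 and 0.25 and did not pass, and neither did HNF4 (−0.69), MEF2 (−0.66) and NR2F/RXR motifs (−1.23), while WT1/EGR motifs (−0.35) passed as distal. WT1/EGR motifs also passed as distal in replicate 1's own list (−0.24), where HNF4 (−0.63) and STAT motifs (−0.18) did not, and GRHL motifs in replicate 2's (−0.80). In a narrower window MEF2 (−0.76), NR2F/RXR (−0.64), POU (−0.30) and STAT motifs (−0.23) did not pass and GRHL motifs (−0.71) did.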

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

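The test on SP/KLF and ETS motifs without NFY was chosen after its result was seen, and the other tests of this part were set before theirs. No biological explanation was tested for the patterns of this part.

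Peaks outside the lists used for the comparisons came to attention in the ranked lists. In replicate 1, 177 peaks were within the IDR threshold in the ranked list but not in its thresholded list, and 41 of them lay on unplaced scaffolds. In replicate 2 there were 177 such peaks, and 51 of them lay on unplaced scaffolds. They included 7 and 6 of the 10 peaks with the highest −log10 p-value of each ranked list.

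The 10 strongest distal regions, near Pak3, Abcb11, Gm5426, Frmd4a, G6pd2, Hic2, Myl12b, Galc, Gphn and Alkbh8, were narrow and mostly intergenic. Of these, 5 had another place in the reference with at least 90% identity, against 16 of 200 other distal regions (8.0%). This met the outcome set beforehand for sequence present elsewhere. The other distal regions were wider, and a match over 50% of the length is then harder to reach. Among the 5, the best identity elsewhere was 92.5% near Myl12b, Galc and Alkbh8, 97.5% near Gphn and 99.7% near G6pd2. The regions near G6pd2 and Galc also matched the mitochondrion. Reads were not analysed, so whether copies shared reads was not tested. Copies of mitochondrial DNA matched 3 of the 10 and 0 of the 200; this lies between the 0 that would argue against the explanation and the 5 that would favour it, so it cannot be told apart for the set. The regions near Pak3, Abcb11, Frmd4a and Hic2 matched neither, and their signal stays without a tested explanation.

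Replicate 2 listed 22091 regions against 14664 in replicate 1, with promoter shares of 54.7% and 70.6%. With its list held to 14664 regions by −log10 p-value, the promoter share of replicate 2 was 69.9%, within 5 percentage points of replicate 1, and by signal it was 64.4%. A longer list that reaches weaker, more distal peaks may therefore account for the lower share. Whether read depth, the number of embryos or the quality of the libraries made the list longer stays open, since the lists carry no counts.

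SP/KLF, NFY and ETS motifs, which were more frequent at promoters, also met the rule at distal summits. Without the 1551 distal regions (13.8%) within 1 kb of any other annotated transcript start, SP/KLF and ETS exceeded every permuted version. Both kept at least 90.3% of their log ratio, which argues against annotated promoters of other transcripts as the whole cause for these motifs. Promoters missing from the annotation were not covered. NFY kept 74.2% of its log ratio and no longer exceeded every permuted version (1.54 against 1.57), so for NFY promoters of other transcripts cannot be told apart from an effect of its own. Against flanks of the same GC content and CpG number the smallest of the 3 ratios was 1.41 (ETS), between the 1.2 that would favour base composition and the 1.5 that would argue against it. The ratio was 6.30 against flanks beside the summits and 1.45 against matched flanks for SP/KLF, 2.71 and 1.41 for ETS, and 1.79 and 2.05 for NFY. The NFY ratio did not fall. However, the matching counted the bases of the motif itself, and the SP/KLF and ETS motifs each hold a CpG. Matching can therefore lower their ratios by itself, so the part due to base composition cannot be told from these values.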

How the results depend on the processing

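Leaving out genes of more than 1 list was chosen after the data were seen, and all other alternatives were set before; the cause of the changes below was not tested. Of 432 values of distal gene lists under an alternative, 356 kept their direction and their side of the threshold, as did 192 of 252 for promoter lists, 199 of 248 for distal motifs and all but 22 of 124 for motifs of promoter against distal summits. The direction turned for 33, 31, 6 and 8 values, of which 28, 26, 6 and 5 passed the threshold neither before nor after. Nephron progenitor (2.27 to 5.28) and podocyte genes (2.11 to 3.62) kept theirs under all 12 alternatives. The overlap of replicate 1 in 2 and of 2 in 1 was 90.1% and 59.8% with reciprocal overlap of at least 50%, 81.0% and 57.2% in lenient lists, 77.7% and 77.2% in equal numbers of strongest regions, 96.3% and 69.7% for single peaks and 95.2% and 63.2% in the stronger part of each list, and that of 2 in 1 was 60.3% with 50% of the region overlapped. Rho was 0.801 in lenient lists, 0.679 with the mean summit signal and 0.772 for distal regions. The promoter share was 25.5% in the lenient replicated set, 71.5% in the stronger part of the conservative set and 54.7 to 70.6% with 1 replicate left out. Replicate-only regions numbered 804 and 8292 against the other's IDR list. In the lenient replicated set 22 distal lists passed (10 in the conservative set); renal vesicle (1.91), ureteric bud (1.88), endothelial (1.72), neural crest (1.41), disease (1.61), Sox (1.45), collagen (1.5) and solute carrier genes (1.12) newly passed as higher, cytochrome P450 (0.443) and keratin-associated genes (0.310) as lower, and skeletal muscle (1.45), ribosomal protein (1.15) and Zfp genes (0.914) turned and passed. Liver genes turned (0.805) without passing. In the same set promoters of nephron progenitor (1.38), ureteric bud (1.37), stroma (1.30), podocyte (1.41), signalling (1.30) and disease genes (1.37) newly passed, those of proximal tubule genes (0.805) no longer did, and those of neural crest (1.07), adrenal (1.01), Hox (1.32), solute carrier (1.1), loop of Henle (1.12), endothelial (1.21), forebrain (1.16), Fox (1.2), Wnt (1.07) and Fgf genes (1.29) turned. Renal vesicle genes also passed in the optimal set (1.71), up to 250 kb (2.02) and with no matching (3.05), as did ureteric bud genes with no matching (2.17). Endothelial genes passed in the optimal set (1.76) and with no matching (1.97) as well, and with no matching collagens (2.20) and disease genes (2.69) also passed, ribosomal protein (0.440) and keratin-associated genes (0.141) passed as lower and Hox genes (1.46) no longer passed. Solute carriers (1.18) and cytochromes P450 (0.561) passed in the optimal set, disease genes up to 250 kb (1.66) and Zfp genes in the stronger part of the set (1.59) and in replicate 1's own list (1.49). Housekeeping genes lost their call under 8 of 12 alternatives and Wnt ligands under 6. In the stronger part of the set, stroma genes no longer passed (1.64), and Hox (0.850), proximal tubule (0.694), adrenal (0.399), skeletal muscle (1.16), forebrain (0.688), pluripotency (1.69), Sox (0.521) and claudin genes (0.393) turned. Without X, Y and close neighbours, Hox (0.648, from 1 gene per cluster) and claudin genes (0.854) turned, and without genes of more than 1 list ureteric bud genes (0.508). Others that turned for distal regions were heart in the optimal set (0.966), skeletal muscle (1.05), pancreas and gut (1.23), pluripotency (1.08) and Zfp genes (0.992) up to 50 kb, and neural crest genes up to 250 kb (0.997). So did neural crest (0.925) and forebrain genes (0.886) over 2.5 kb from a start, pancreas and gut (1.23) and pluripotency genes (1.02) matched on an open promoter, and pancreas and gut (1.24) and Zfp genes (0.986) with no matching. Promoter ratios that turned were those of ureteric bud (0.893) and collagen genes (0.947) with a narrower promoter, and of Hox (1.09), collagen (0.979) and solute carrier genes (1.01) in the optimal set. Matched on promoter GC content, those of nephron progenitor (0.943), renal vesicle (0.90), ureteric bud (0.842), podocyte (0.999), signalling (0.823), Sox (0.850) and collagen genes (0.955) turned, and 7 uncalled lists passed as lower (0.429 to 0.853). Without genes of more than 1 list, those of nephron progenitor (0.873), ureteric bud (0.913) and signalling genes (0.827) turned. Without 1 replicate, distal ratios were 0.484 to 0.924 for proximal tubule, 0.853 to 0.898 for forebrain, 0.557 to 1.16 for pluripotency and 0.974 to 2.27 for cell cycle genes. Promoter ratios were 0.473 to 0.812 for collagens, 0.886 to 0.908 for ureteric bud, 0.984 to 1.00 for signalling and 0.90 to 1.03 for Sox genes. The NR2F/RXR motif had 0.539 to 1.53, and log2 differences were −1.24 to 0.11 for NR2F/RXR, −0.24 to 0.007 for WT1/EGR, −0.58 to 0.03 for RFX and −0.88 to 0.41 for REST motifs. With 1 summit per region, the POU, STAT and RFX differences turned (0.14, 0.25 and 0.31), as did RFX with a narrower window (0.11). Motif ratios that turned were HNF4 (1.17) and NR2F/RXR (0.765) with that window, HNF4 (1.12) and MEF2 (1.03) with a wider one and NR2F/RXR (0.931) with farther flanks. Between 14 and 18 distal motifs met the rule, and 16 to 25 Hox genes had a promoter region. Unknown read depth limits all counts, since a deeper library lists more regions.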

Other observations

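The SIX1/SIX2 test of this part was set before its result was seen, and the counts by chromosome were added after the data were seen. Open regions were unevenly spread over the chromosomes. Chromosome 11 held 1695 conservative regions, or 14.3 per Mb of ungapped sequence, and chromosome 14 held 868, or 7.15 per Mb, the highest and lowest among the autosomes. The X chromosome held 609 (3.73 per Mb, 421 in replicate 1 and 593 in replicate 2) and the Y chromosome 9 (0.102 per Mb, 5 and 7). Both replicates were pools of male and female embryos, and the lists carry no counts to relate these densities to copy number. Per protein-coding gene, chromosome 18 held 1.52 regions, chromosome 7 held 0.819 and the X chromosome 0.642.

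A hypothesis was that SIX1/SIX2 motifs mark the distal regions of nephron progenitor genes, since Six2 is expressed in these cells and the SIX1/SIX2 motif was more frequent at distal summits. Of the 51 distal regions of nephron progenitor genes, 0 had a SIX1/SIX2 motif at a summit, against 265 of 8751 other assigned distal regions (3.03%), with a two-sided Fisher's exact p of 0.407. A share at or below that of the other regions had been set beforehand as the outcome against the hypothesis, and it was met. However, the exact 95% upper limit of the share, 6.98%, includes that of the other regions, so the question stays undecided. A share above 6.98% lay outside the interval, while a share below that of the other regions was not detectable with 51 regions. Regions with the motif in other kidney lists were 2 of 27 for renal vesicle genes (near Bmp2 and Cdh4), 1 of 43 for stroma genes (near Aldh1a2) and 1 of 19 for loop of Henle genes (near Esrrg), with an adjusted Fisher's exact p of 1.0 for each; these genes were chosen after their values were seen.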
